A study of Xenopus laevis with 6 samples.

How the data were processed

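Total RNA of 6 samples of cultured animal pole explants was measured, 4 untreated and 2 from embryos injected with NICD. Per the labels' protocols, 1 µg of total RNA was amplified to biotinylated cRNA and hybridised to an Affymetrix Xenopus laevis array. The series design text calls the untreated explants pooled. The deposited values are MAS5 signal intensities per probe set on a linear scale, per the submitters' processing notes, which name MAS5; its version is not given in the sources used here. In each of the 6 columns the mean after leaving out the lowest and highest 2% of probe sets was about 500, so the authors' values had already been scaled per array; scaling to 500 was repeated and left them in proportion. MAS5 subtracts mismatch probe signals, which makes low signals noisy. The 3' to 5' ratio of the gapdh control and other array values were taken from the same table. The deposited experiment files of the arrays hold other values, the settings of station and scanner, per the file headers; they were used to find the processing day, chip lot and fluidics module. All arrays came from 1 chip lot and were processed on 2 days.

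The table held 15611 probe sets, of which 120 controls were left out, leaving 15491. No value was missing. Of these, 9304 had 1 gene symbol in the platform annotation, 195 had several and 5992 had none; probe sets with several symbols were not named. Symbols were brought up to date through the gene number for 9227 probe sets with a RefSeq table of the assembly Xenopus_laevis_v10.1, giving 7531 distinct symbols. No genome build of the array's design was used, so no coordinates are given.

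A probe set was tested if its signal was above the 40th percentile of its array in at least 2 arrays. The log2(signal + 32) values of the 10368 probe sets kept were fitted with limma 3.58.1 (R 4.3.3; lmFit, then eBayes with a mean-variance trend, 2-sided), NICD against untreated with no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Gene lists were tested with limma's camera on 1 probe set per symbol, the one with the highest mean, with a preset correlation of 0.01, adjusted over the 15 lists. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Means and SDs of signals are on the linear scale.

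The grouping, the test, the 15 gene lists (687 gene names), the rule for named genes and most of the alternative settings were fixed before the data were examined. The lists cover Notch targets, Notch pathway components, multiciliated cells, ionocytes, goblet and small secretory cells, epidermis, neurons, neural progenitors, glia, neural crest, mesoderm with muscle and blood, endoderm, cement and hatching gland, proliferation, and stress with cell death. The named genes are those with 1 symbol, past the test and with both NICD arrays outside the untreated range that had the 10 largest increases and 10 largest decreases, every tested Notch target, up to 4 members per other list with the largest change past the test, and the notch1 probe sets. Further list members were named after their values were seen: pmp22.S, sox9.S, gpm6b.S, mbp.S, sox2.L, the cldn6.1 copies, ca4.1.S, xbp1.L, foxa1.S, neurod1.L, tubb2b.S, vegt.S, ckm.L, tnni2.S, the ag1 copies, pax3.L, ccna1.L, chek1.S, hsp70.L and ddit4.S. The synonym matches of 4 list names to other genes were left out before values were seen.

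The processing day was entered as a block, and each change was also computed within each day. The procedure was tested on simulated data for this comparison, with 4 and 2 simulated arrays and 9951 probe sets: 51.0% of 2-fold and 100% of 4-fold changes were called, 5.63% of the calls were unchanged probe sets, and 1.50% of 200 lists of unchanged genes had a camera p under 0.05. The simulated probe sets varied independently of each other and without a day difference, so the last rate does not check camera's preset correlation. Far fewer of them were changed than in the data, so the other rates need not carry over. The alternative settings fixed beforehand were quantile normalization, median centring, pseudocounts of 1 and 80, no filter and a filter at the 60th percentile, eBayes without a trend, array quality weights, the replicate number as a block, the day as a block, each array left out, a 2-fold minimum, an adjusted p under 0.10, camera with an estimated correlation and the mean over all probe sets of a gene. Settings added after seeing the data were probe sets without a shared-probe suffix, NICD arrays left out on the probe sets tested with all arrays, and the day block with an estimated correlation. With an array left out of the NICD group, the lone array was assumed to vary like the others.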

Results

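The series measured transcript levels in animal pole explants of the frog Xenopus laevis. The animal pole is the upper part of the blastula; cut out and cultured alone it forms epidermis with ciliated, ionocyte and secretory cells. The explants were cut at stage 8 and cultured until sibling embryos had reached stage 20. Explants came either from untreated embryos (4 samples) or from embryos injected with NICD (2 samples), the Notch intracellular domain, which is the part of the receptor that enters the nucleus and switches on target genes. Each sample was hybridised to 1 Affymetrix Xenopus laevis array. The median signal per array lay between 153.9 (NICD 2) and 177.4 (untreated 3), and between 14.4% and 16.7% of probe sets per array had a signal under 32. The number of arrays, 4 and 2, limits the precision of every value. The labels do not say that the samples of a group came from separate experiments, so p-values measure the spread between these samples, which may be technical. The 3' to 5' signal ratio of the gapdh control was 2.70 to 3.54 in the untreated arrays, 4.21 in NICD 1 and 2.98 in NICD 2; that of the actb control was 0.092 to 0.199 in the untreated arrays, 0.151 in NICD 1 and 0.113 in NICD 2. Gene symbols end in .L or .S for the 2 related copies (homeologs) that Xenopus laevis carries of many genes; their sequences are close, so a probe set named for 1 copy can also detect the other.

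The comparison of NICD explants with untreated explants asks which genes differ after injection of NICD in this ectoderm, in a series titled for the role of Notch in glial development. No sample is labelled as injected with a control, so effects of NICD and of the injection itself cannot be told apart. Genes of the hes5 family, which encode transcriptional repressors switched on by Notch, were among the largest increases. The hes5.1.L signal was 16.8 ± 3.58 (SD, n = 4) in untreated and 9481 ± 2431 (SD, n = 2) in NICD explants, a log2 change of 7.59. In the other direction, val.L fell from 6678 ± 2575 (SD, n = 4) to 59.8 ± 23.8 (SD, n = 2), a log2 change of -6.13. The secreted lectin itln1.L, made by goblet cells, fell from 23300 to 475 (log2 change -5.96), and foxi1.L, a regulator of ionocytes, from 2273 to 29.8 (-5.26). Of 28 neural progenitor genes tested, 18 rose, zic2.L among them (20 of 44 with no filter on low values). Of 47 multiciliated cell, 26 ionocyte and 5 secretory cell genes 34, 20 and 3 fell, with 1 ionocyte gene higher. These 4 list shifts passed limma's camera at its preset correlation and did not at an estimated one (adjusted p = 0.168, 0.0602, 0.0541 and 0.217).

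Of 10368 probe sets tested, 3275 changed at an adjusted p under 0.05 in limma (31.6%), 1591 higher and 1684 lower in NICD explants. Changes of at least 2-fold were found for 2286 of these, 1016 higher and 1270 lower, and of at least 4-fold for 652. All changes are on the log2(signal + 32) scale, which understates the change of genes with low signals. Where 1 group lies near background, as for hes5.1.L or odf3.L, the size and rank of the change depend on the pseudocount. The median log2 change of all tested probe sets was 0.05. The arrays were processed on 2 days, untreated 1, untreated 2 and NICD 1 on the first and the others on the second. Each day held 2 untreated arrays and 1 NICD array, so the day as a block left the log2 changes as they were and altered their errors. With that block 4172 probe sets changed, 2115 higher and 2057 lower, and they included all 3275. Across all tested probe sets the changes of the 2 days correlated with Pearson's r = 0.85 and Spearman's rho = 0.77 (probe sets are not independent replicates). Without NICD 1 the count of higher probe sets was 927 (1161 on the probe sets tested with all arrays), and without NICD 2 it was 530 (757), with 883 lower and 1413 changed in all, compared with the same 4 untreated arrays. Both NICD arrays were washed in fluidics module 4 and no untreated array was, so module and treatment cannot be told apart.

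**Figure D1:**
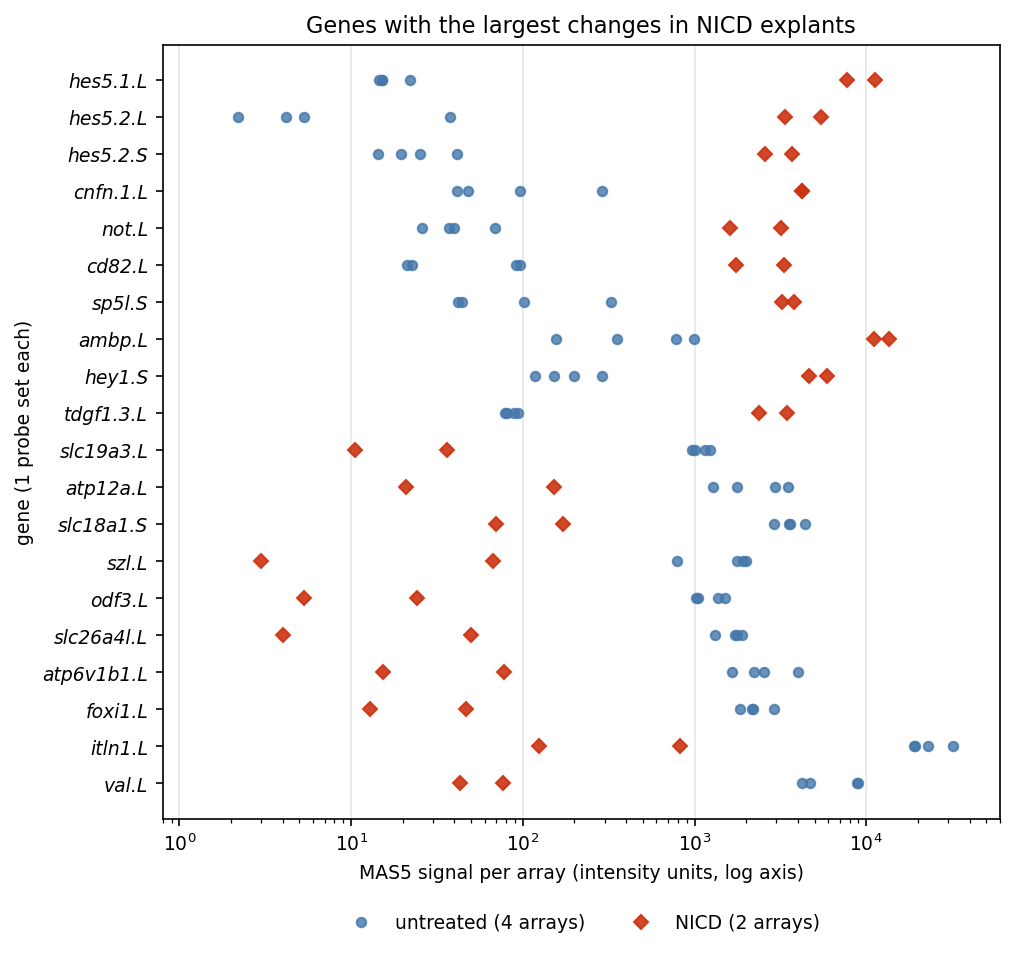
MAS5 signal per array (log axis, intensity units) for the 10 genes with the largest increase and the 10 with the largest decrease, 1 probe set per gene, in the 4 untreated arrays (circles) and the 2 NICD arrays (diamonds). Genes were eligible only if both NICD arrays lay outside the untreated range; the mean moves from 16.8 to 9481 for hes5.1.L and from 6678 to 59.8 for val.L.

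**Figure D2:**
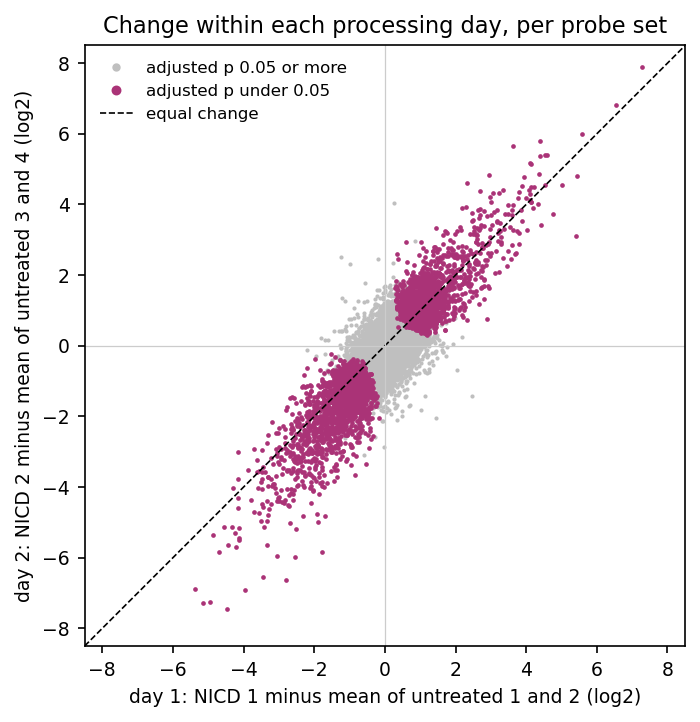
Log2 change of each tested probe set on day 2 (NICD 2 minus the mean of untreated 3 and 4) against that on day 1 (NICD 1 minus the mean of untreated 1 and 2), with the 3275 probe sets past the test in colour and equal change as a dashed line. The coloured points were chosen by a test on the mean of both days, so their equal sign on the 2 days follows from the choice.

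Among the other large increases, cnfn.1.L changed by 5.09 on the log2 scale, cd82.L, a membrane protein of the tetraspanin family, by 4.89, and ambp.L by 4.64. For ambp.L, 2 of the 4 tested probe sets had the opposite sign. The homeobox gene not.L, known from the notochord and the early organizer, rose by 4.97, sp5l.S, a zinc finger gene downstream of Wnt, by 4.78 and tdgf1.3.L, a co-receptor of Nodal signalling, by 4.62. Large decreases included slc26a4l.L (-4.96), an anion exchanger of the pendrin type, and atp12a.L (-4.50), a proton-potassium pump. The BMP-induced antagonist szl.L changed by -4.73, odf3.L by -4.78, the monoamine transporter slc18a1.S by -4.65 and slc19a3.L, a thiamine transporter, by -4.38. The largest adjusted p of these named genes in limma was 0.000235 (ambp.L).

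Of the 14 Notch target genes tested, 11 rose and none fell, with 11 also higher when adjusted over the list alone and 0 lower in limma at an unadjusted p under 0.05. Their median log2 change was 2.70, with 2.28 on day 1 and 3.25 on day 2. It covers only the members that passed the filter on low values. With no filter 12 of 19 rose and none fell. After hes5.1.L the largest changes were those of hes5.2.L (6.67 ± 0.34, SE), hes5.2.S (5.79 ± 0.27) and hey1.S (4.63 ± 0.31), a relative of the hes genes. Next came hes5.10.L (4.08), hes5.3.L (3.35), hes5.6.L (3.14), hes4.S (2.27) and nrarp.S (2.24), a feedback inhibitor of Notch. Smaller increases were those of hes5.5.S (1.07) and hes4.L (0.83, adjusted p = 0.00962 in limma, but 0.0780 without NICD 1). The remaining members did not pass: hes1.S changed by 0.58, esr-5.L by 0.43 and hes1.L by -0.28. The list stood above the other genes in limma's camera with its preset correlation of 0.01 (adjusted p = 9.50e-09, and 7.58e-08 with the day as a block), but adjusted p = 0.0541 with an estimated correlation. Leaving out NICD 1 left 3 higher members and leaving out NICD 2 left 4, because a gene high in a single array then missed the filter on low values; on the probe sets tested with all arrays, an alternative chosen after seeing the data, 10 and 11 were higher.

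**Figure D3:**
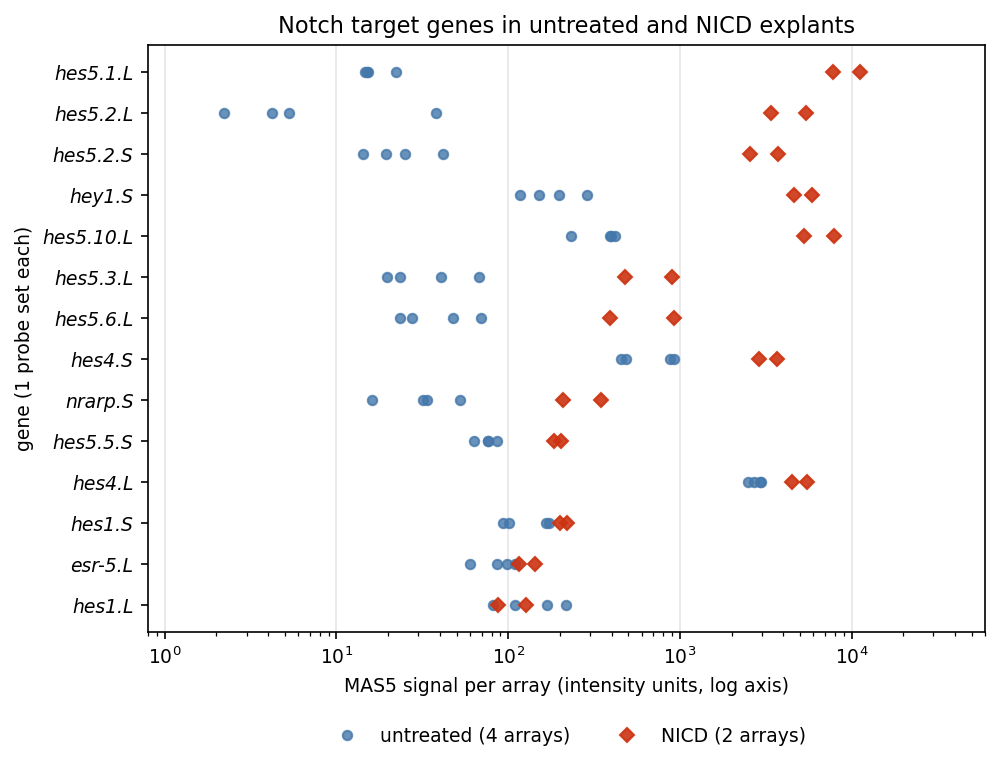
MAS5 signal per array (log axis, intensity units) of the 14 tested Notch target genes, ordered by log2 change, in 4 untreated (circles) and 2 NICD arrays (diamonds). The 11 genes at the top, from hes5.1.L to hes4.L, passed the test; hes1.S, esr-5.L and hes1.L did not.

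Components of the Notch pathway moved in both directions. Of 12 tested, 2 rose and 4 fell, the same counts as when adjusted over the list alone. The ligand jag1.L rose by 2.1 ± 0.26 (SE), whereas the Delta ligands dll1.L (-2.27 ± 0.31) and dlc.L (-1.52 ± 0.29) and furin.L (-2.86), a protease that cleaves the receptor, fell. The notch1.S probe set rose from 257 ± 42.4 (SD, n = 4) to 665 ± 313 (SD, n = 2), a log2 change of 1.2 (adjusted p = 0.0105 in limma; 1.70 on day 1, 0.70 on day 2). Whether this probe set lies in the injected part of the transcript is not known here, so it does not check the labels. Without NICD 1 its log2 change was 0.73 with an adjusted p of 0.114 in limma and 1 member was higher; without NICD 2 or either of untreated 2 and 4, 2 were lower, and without NICD 2 the adjusted p of dlc.L was 0.0549 in limma. The list as a whole had a median of -0.18 (-0.11 on day 1, -0.04 on day 2; adjusted p = 0.444 in limma's camera, 0.560 with the day as a block).

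Most tested genes of the differentiated cell types of the larval skin fell. Of 47 multiciliated cell genes, 34 fell and none rose (38 lower when adjusted over the list alone), with a median of -1.43, and -1.20 and -1.52 on days 1 and 2. They included ccno.L (-4.20 ± 0.33, SE), needed to make the many centrioles of these cells, the axoneme components cfap52.S (-3.68) and spag6.L (-3.58), and the centrin cetn4.L (-3.59). Of 26 ionocyte genes 20 fell and 1, ca4.1.S (0.95), rose, with 21 lower when adjusted over the list alone and a median of -1.20 (-1.0 and -1.25 on days 1 and 2); without NICD 2, 13 were lower, and no member was called higher when NICD 2, untreated 1, untreated 2 or untreated 3 was left out, with no filter, or with the filter at the 60th percentile. The proton pump subunit atp6v1b1.L changed by -5.12 ± 0.40 (SE), carbonic anhydrase ca2.L by -4.17 and the transcription factor ubp1.L by -3.70. Of 5 goblet and small secretory cell genes tested, itln1.L (-5.96) and both copies of agr2, agr2.L (-3.08) and agr2.S (-1.62), fell. Adjusted over the list alone 4 were lower, with xbp1.L (-0.82) joining them. The change of foxa1.S was -0.007 and not past the test, and tph1.L and slc18a2.L were not tested. The fall of this list thus rests mainly on itln1 and agr2. The median was -1.62 (-1.17 and -2.08 on days 1 and 2). In limma's camera the adjusted p was 8.13e-17 for the multiciliated, 1.15e-10 for the ionocyte and 0.00180 for the secretory list, and with the day as a block 4.29e-17, 1.56e-10 and 0.00300. Limma's camera gave an adjusted p of 0.0602, 0.0541 and 0.217 with an estimated correlation, in the same order. The 1 NICD array with a gapdh ratio above the untreated range, NICD 1, had the smaller decreases of these lists.

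**Figure D4:**
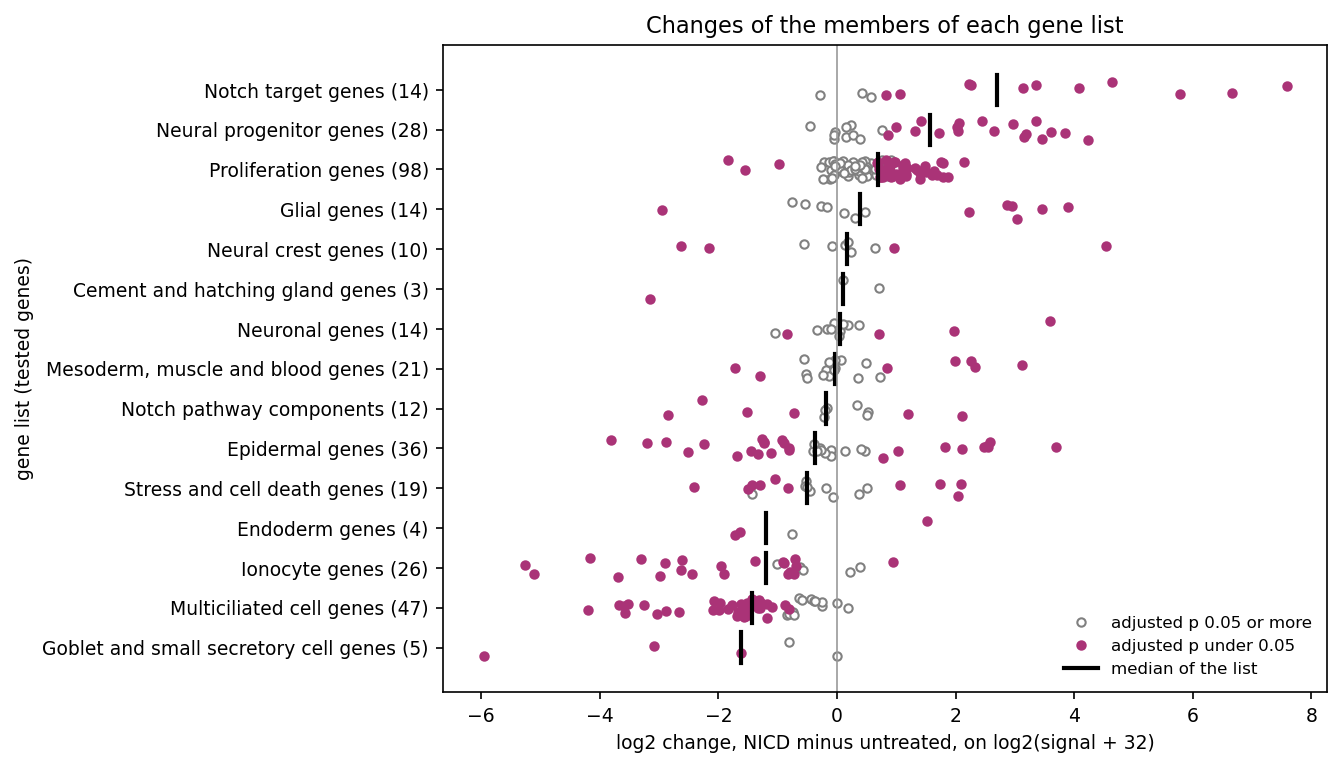
Log2 change (NICD minus untreated, on log2(signal + 32)) of each tested member of the 15 gene lists, with members past the test filled, the others open, and the median of each list as a bar; the number of tested genes follows each name. The medians run from -1.62 (goblet and small secretory cell genes) to 2.70 (Notch target genes).

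General epidermal genes were divided. Of 36 tested, 9 rose and 16 fell, also when adjusted over the list alone. Keratin krt12.4.S, a major keratin of the outer layer, changed by -3.80 ± 0.77 (SE), with -1.77 on day 1 and -5.84 on day 2. The transcription factor gata2.L (-3.21) and the cornified envelope component ppl.L (-2.88) also fell. Keratin krt18.1.S, of the simple epithelial type, rose by 3.69 ± 0.44 (SE), as did the tight junction genes cldn6.1.L (2.58) and cldn6.1.S (2.55). The median of the list was -0.37 (-0.28 and -0.61 on days 1 and 2; adjusted p = 0.0864 in limma's camera, 0.101 with the day as a block). Without NICD 1 the median was -0.67, with an adjusted p of 0.0343 in limma's camera, and without NICD 2 it was -0.24, with 7 members lower instead of 16.

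Of 28 neural progenitor genes tested, 18 rose and none fell (19 higher when adjusted over the list alone). Their median was 1.57, with 1.91 and 1.16 on days 1 and 2. A gene near background in untreated explants passed the filter only if both NICD arrays lay above it, which favours genes that rose. With no filter on low values 20 of 44 rose and none fell. The increases included the zinc finger genes zic2.L (4.24 ± 0.29, SE) and zic2.S (3.45), both copies of geminin, gmnn.S (3.85) and gmnn.L (3.61), and sox2.L (3.36). The adjusted p was 3.60e-08 in limma's camera (1.03e-07 with the day as a block), but limma's camera gave adjusted p = 0.168 with an estimated correlation. Without NICD 1 the filter left 9 higher members and without NICD 2 it left 11; on the probe sets tested with all arrays 13 and 17 were higher.

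Of 14 neuronal genes, 3 rose and 1 fell, the same counts as when adjusted over the list alone, and 10 were not past the test. With no filter on low values 2 of 48 neuronal genes rose and 2 fell. The intermediate filament genes prph.S (3.59 ± 0.41, SE) and prph.L (1.97) rose, gap43.L rose by 0.70 and the synaptic vesicle gene syt1.L fell by 0.84 on the log2 scale. The proneural gene neurod1.L changed by -0.11 and the tubulin tubb2b.S by 0.37, neither past the test. The median was 0.04 (0.23 and -0.07 on days 1 and 2; adjusted p = 0.790 in limma's camera, 0.904 with the day as a block). The call for gap43.L (adjusted p = 0.0440 in limma) was lost in 13 alternatives, among them quantile normalization, median centring and each array left out. That for prph.L ended without NICD 2 and that for syt1.L without NICD 1, and 0 members were higher without NICD 2 (1 on the probe sets tested with all arrays).

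Of 14 glial genes, 6 rose and 1 fell, also when adjusted over the list alone. The rise was in pmp22.L (3.90 ± 0.42, SE), a myelin protein of peripheral nerve also found in epithelia, pmp22.S (2.87), vimentin (vim.S 3.45, vim.L 3.04), sox9.S (2.95) and gpm6b.S (2.23). Vimentin and sox9 are also expressed by neural precursors and other embryonic cells. The astrocyte enzyme aldh1l1.L, which is not restricted to glia, fell from 3376 ± 446 (SD, n = 4) to 439 ± 251 (SD, n = 2), a log2 change of -2.96. Myelin basic protein, mbp.S, changed by 0.31 and was not past the test. The 14 are only the members that passed the filter on low values. With no filter 7 of 23 glial genes rose and 1 fell. The list had a median of 0.39 (0.45 and 0.33 on days 1 and 2; adjusted p = 0.0864 in limma's camera, 0.131 with the day as a block).

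Markers of other tissues were included because explants can hold or form them. Of 10 neural crest genes, 2 rose and 2 fell, led by pax3.S (4.54 ± 0.24, SE) and msx2.L (-2.63 ± 0.30), followed by ets1.L (-2.16) and the pigment cell gene pmel.S (0.96). The pax3.L probe set tested for this list changed by -0.55 and was not past the test, and another pax3.L probe set had the opposite sign (1.97). The median of the list was 0.17 (0.23 and 0.07 on days 1 and 2), opposite in sign to the direction of limma's camera (adjusted p = 0.999, 0.985 with the day as a block). Of 21 mesoderm, muscle and blood genes, 5 rose and 2 fell. The early mesoderm genes vegt.L (2.33 ± 0.27, SE), vegt.S (0.84), tbxt.S (2.26 ± 0.27), the brachyury gene, and wnt8a.L (1.99 ± 0.25) rose, as did the matrix gene sparc.S (3.11), while the muscle genes ckm.L (-1.72) and tnni2.S (-1.31) fell. The median of that list was -0.03 (-0.06 and 0.03 on days 1 and 2) and limma's camera pointed up (adjusted p = 0.692, 0.759 with the day as a block). Of 4 endoderm genes gata6.L (-1.72) and gata5.S (-1.63) fell and cndp1.L (1.52) rose, with a median of -1.20 (-1.05 and -0.92 on days 1 and 2; adjusted p = 0.255 in limma's camera, 0.204 with the day as a block). Of 3 cement and hatching gland genes the hatching enzyme astl2d.1.L fell (-3.16), and ag1.L (0.71) and ag1.S (0.10) were not past the test; the median was 0.10 (-0.86 and 0.18 on days 1 and 2) while limma's camera pointed down (adjusted p = 0.444, 0.560 with the day as a block). Adjusted over the list alone, the counts of these 4 lists were the same. With no filter on low values 2 of 20 neural crest genes rose and 3 fell. Of 70 mesoderm, muscle and blood genes 5 then rose and 3 fell. Of 29 endoderm genes 2 rose and 3 fell, and of 6 cement and hatching gland genes 1 rose and 1 fell. Without NICD 2 the calls for pmel.S and cndp1.L ended (adjusted p = 0.159 and 0.126 in limma), and without either NICD array in turn 3 mesoderm, muscle and blood genes were higher. Of the neural crest genes 1 was higher without NICD 1 and 0 without NICD 2 (2 and 1 on the probe sets tested with all arrays).

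Of 98 proliferation genes, 43 rose and 3 fell (50 higher and 3 lower when adjusted over the list alone), with a median of 0.69, and 0.66 and 0.62 on days 1 and 2. The replication genes cdc6.L (2.14 ± 0.31, SE), pcna.L (1.87 ± 0.24) and rfc4.L (1.79) led the increase. The cyclin ccna1.S, of the early embryonic type, fell by 1.84 on the log2 scale, its copy ccna1.L by 1.55 and chek1.S by 0.98. The adjusted p was 2.33e-07 in limma's camera (1.03e-07 with the day as a block), but limma's camera gave adjusted p = 0.168 with an estimated correlation. Without NICD 2 the number of higher members was 21, and 25 on the probe sets tested with all arrays.

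Of 19 stress and cell death genes, 4 rose and 6 fell, also when adjusted over the list alone. The chaperone of the endoplasmic reticulum hspa5.L (-2.41 ± 0.58, SE), hsp70.L (-1.51) and ddit4.S (-1.43) fell, and heme oxygenase hmox1.L (2.1 ± 0.33), sesn1.L (2.04) and gadd45a.S (1.74) rose. The median was -0.51 (-0.14 and -0.84 on days 1 and 2; adjusted p = 0.396 in limma's camera, 0.296 with the day as a block). Without NICD 2, 1 member was lower and the call for hspa5.L was lost (adjusted p = 0.161 in limma).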

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

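The tests of array response at the highest signals, array scaling, RNA degradation and carried-over muscle were chosen after the results they concern had been seen, as was the comparison with other groupings of the arrays; those of the array response between days over the whole range and of slower development were written before.

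In 5 of 94 sets of 4 untreated values (named genes and list means), 1 array lay apart from the others by more than Dixon's critical value for 4 values, where chance gives about 1 in 20. For hes5.1.L the ratio of gap to range was 0.914 (untreated 2 apart), for hes5.2.L 0.878 (untreated 4), for hes5.10.L 0.878 (untreated 1), for the BMP antagonist szl.L 0.863 (untreated 3) and for gata5.S 0.856 (untreated 2).

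The splits of the 6 arrays into 4 and 2 number 15, too few for a share under 0.05. The real split gave 3275 changed probe sets and the highest of the others 0 in limma (4389 and 1289 at an unadjusted p under 0.05), so 1 split, the real one, had as many. Each of the other splits puts at least 1 NICD array with untreated arrays, which widens the spread within that group, and the splits do not keep to the processing day, so low counts were to be expected of them and the comparison decides nothing.

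The first pattern weighed is that most changes were larger in NICD 2 than in NICD 1. Among changed probe sets 68.9% had the larger change on day 2, and the median size was 1.24 times that of day 1, 1.13 times for higher and 1.35 times for lower probe sets. The pattern did not hold for every list. Medians were larger on day 1 for neural progenitor (1.91 against 1.16) and proliferation genes (0.66 against 0.62). They were larger on day 2 for the Notch target, multiciliated, ionocyte and secretory lists. A wider array response on day 2 would spread the untreated arrays of that day more widely too. The ratio of their SDs over probe sets, day 2 over day 1, was 0.983 (bootstrap interval over probe sets 0.978 to 0.988). For these untreated arrays that argues against a wider response over the whole range. The interval covers the choice of probe sets and not the spread between the few arrays of each day. The day 2 arrays did have higher maxima (37591, 41993 and 39192 against 21978, 23904 and 28797) and larger shares of signal in the top 100 probe sets (16.2% to 17.8% against 13.9% to 14.0%). Among the 3067 changed probe sets under 5000 in every array the day 2 changes were still 1.22 times as large (bootstrap interval over probe sets, not arrays, 1.19 to 1.25). That argues against the highest signals as the whole cause. A difference in injected dose or in tissue between the NICD samples, or in the response of the NICD 2 array alone, stays open and was not tested, since each day held 1 NICD array.

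The second pattern is the fall of genes of multiciliated cells, ionocytes and secretory cells, the last resting mainly on itln1 and agr2. Array scaling as its cause is argued against, since under quantile normalization and median centring the highest of the list medians was -1.18. RNA degradation stays open, by a rule made stricter after the values were seen: 1 NICD array had a gapdh ratio above the untreated range, while both had an actb ratio within it (0.151 and 0.113 against 0.092 to 0.199). In every array the actb ratio was far below 1, with its 3' signal under its 5' signal. It is therefore a doubtful measure of degradation and does not weigh against the gapdh ratio. Slower development of the whole explant may also contribute: 0 of 6 early embryonic genes not looked at before were past the test and higher in limma (1 at an unadjusted p under 0.05), but the exact binomial upper bound is 45.9%, 3 of the 6 had mean signals under 200, and the 14 early genes that rose had all been seen before that list was written. That bound counts foxi4.2.L and foxi4.2.S, copies of 1 gene, as separate, so it may be too low. The bound was added after the 0 was seen (by the rule as first written, under 25%, the test would have counted against slower development), and the injection of NICD, the difference the design names, stays open as well.

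The third pattern is the rise of not.L, tbxt.S, wnt8a.L and vegt.L, genes of early mesoderm; the explanation tested was narrowed to differentiated muscle after the values were seen. The explants were cut from the blastula at stage 8, before muscle differentiates, so none could be carried in. The design fixed the outcome of that test, and its values show only whether muscle genes were higher at harvest. The muscle and notochord list was written after the rise was seen, and its 7 tested members are all muscle genes. They had a median log2 change of -0.0564 and a highest change of 0.73 (myod1.S), against at least 1.99 for the 4 genes to be explained. In limma 2 were lower and 0 higher (1 higher at an unadjusted p under 0.05). Of the 7, 4 had mean signals under 200, but the 2 with the highest signals, ckm.L (-1.72) and tnni2.S (-1.31), fell. These 2 thus did not rise. In the untreated arrays other muscle genes were low: 5 probe sets below the filter had signals of at most 212.3. Whether the signals of ckm.L and tnni2.S came from muscle is not known here, so their fall decides nothing about muscle. The 4 genes to be explained are genes of early mesoderm, so values of muscle genes cannot show where their rise came from. Further probe sets chosen after their values were seen and below the filter, 5 of muscle genes (NICD signals of at most 55.4) and 5 of the notochord and organizer genes col2a1.S, shh.L, nog.L and chrd.1.S (at most 86.9), lie too near the floor to exclude either tissue. Notochord and other early mesoderm stay open.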

How the results depend on the processing

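The alternatives without a shared-probe suffix, with probe sets kept as with all arrays, and with the day block and an estimated correlation were chosen after seeing the data. No list shift or named gene past the test changed direction under the alternatives run, but the balance of calls turned from fewer higher than lower (1591 and 1684) to more with the day block (2115 and 2057), without untreated 3 (1547 and 1543) and at an adjusted p under 0.10 in limma (2110 and 2023). Leaving out 1 array at a time gave 1413 to 3090 changed probe sets, 530 to 1547 higher and 883 to 1553 lower, the lowest each time without NICD 2; without NICD 1 there were 927 higher. On the probe sets tested with all arrays, 2601 changed (1161 higher, 1440 lower) without NICD 1 and 1684 (757 higher, 927 lower) without NICD 2, so part of each drop comes from the filter. With a 2-fold minimum 1016 were higher. The day block added list calls, most of them for proliferation genes (54 higher against 43) and multiciliated cell genes (39 lower against 34). It also gave 22 lower ionocyte genes against 20 and 8 lower stress and cell death genes against 6. With an estimated correlation, adjusted p in limma's camera rose above 0.05 for 6 lists, with unchanged medians of 2.70 (Notch targets), -1.43 (multiciliated), -1.20 (ionocyte), -1.62 (secretory), 1.57 (neural progenitor) and 0.69 (proliferation), and so it did with the day as a block as well. The epidermal list passed the test in 3 settings, without the shared-probe suffix (median -0.41, adjusted p = 0.0232 in limma's camera) and without NICD 1 with either filter (-0.67); over arrays left out its median ran from -0.67 to -0.24, and over its alternatives the adjusted p from 0.0213 to 0.624. Of values for named genes under alternatives, 1432 stayed on their side of the threshold, 28 lost it and 1 gained it; 13 of the losses were gap43.L, and hes4.L, syt1.L and notch1.S lost it without NICD 1, and dlc.L, prph.L, pmel.S, cndp1.L and hspa5.L without NICD 2. Causes were not tested, apart from the filter, which drops genes high in a single array. Where 1 group lies near background the size of a change depends on the pseudocount: with 1 and with 80 added, it was 9.06 and 6.60 for hes5.1.L, 9.07 and 5.58 for hes5.2.L, -6.60 and -3.79 for odf3.L, and -5.42 and -2.76 for ubp1.L, and with 1 hes5.2.L ranked above hes5.1.L.

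The labels give replicate numbers to both groups without saying that they pair samples, and with 2 shared numbers the data cannot show it: deviations from the group means correlated at 0.20 for number 1 and -0.23 for number 2. The signs followed the processing day. NICD 1 correlated at 0.20 and 0.23 with untreated 1 and 2, and at -0.12 and -0.28 with untreated 3 and 4. The values of NICD 2 are these with the sign turned. With the replicate block 3021 probe sets changed, 1491 higher and 1530 lower. In that fit untreated 3 and untreated 4, whose numbers no NICD array shares, add nothing to the estimated change.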

Other observations

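The lists described here were written after values had been seen, so their counts and medians are descriptions and no list test is given. Of 20 tested genes of a blastula and gastrula list, 14 rose in NICD explants and none fell, but those 14 are the members whose values had been seen before the list was written; of the other 6, 0 rose in limma (1 at an unadjusted p under 0.05). Besides not.L, sp5l.S and tdgf1.3.L, the 14 included foxb1.S (4.21 ± 0.23, SE) and pou5f3.2.L (3.09 ± 0.28), a relative of the mammalian pluripotency factor Oct4. The siamois gene sia1.L (0.27) and nodal2.L (0.07) were not past the test. Geminin, sox3, wnt8a, tbxt and vegt of this list also belong to the neural progenitor or mesoderm lists.

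Of 30 tested BMP pathway genes and targets, 15 fell, 4 rose and 11 were not past the test, with a median log2 change of -0.97. Decreases included tbx3.S (-4.08 ± 0.25, SE), the ligand bmp7.1.L (-3.94 ± 0.31), the pseudoreceptor bambi.L (-3.41) and bmp4.S (-2.17), and the increases were bmp7.2.L (2.27) and the ventx genes ventx2.2.L (1.64), ventx2.1.L (1.18) and ventx3.2.S (0.89). Of 14 tested Wnt targets and pathway genes, 11 rose, fzd8.S (-0.89) fell, and the median was 1.84. The caudal genes cdx1.S (4.36 ± 0.72, SE) and cdx4.L (3.53 ± 0.47), the receptor fzd7.L (3.97 ± 0.27), sfrp2.S (3.52) and axin2.L (1.13 ± 0.30), a feedback gene of the pathway, rose. The notochord and muscle list had 7 tested genes with 2 lower and 0 higher. The BMP and Wnt lists share members with other lists and are not separate evidence. Of the BMP list, gata2, gata3 and msx1 are also epidermal, msx2 and id3 neural crest and id4 glial members. Of the Wnt list, ccnd1 is also a proliferation, wnt8a a mesoderm and sp5l a blastula and gastrula member.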
